A study of Drosophila melanogaster with 3 samples.

How the data were processed

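ChIP-seq of a Zfh1 fusion with enhanced green fluorescent protein was done on chromatin of whole embryos of 0 to 24 h, in 3 biological replicates named as separate by the labels. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The replicate numbers come from the labels' descriptions. No value column was left without a sample or a pooled group.

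The authors deposited a ranked and a thresholded peak list for each replicate, made from the alignments of that replicate and a further alignment file, and 4 ranked and 4 thresholded lists for the whole series. The lists are in dm6 coordinates, per the labels and the file names. The aligner, the peak caller and their versions are not given in the sources used here, and read counts per library were not used here, so depth is unknown and no value is scaled by it. The lists hold an irreproducible discovery rate (IDR), which measures how well peak ranks agree between 2 sets of reads. Each deposited score is the authors' IDR of a peak scaled to at most 1000. The deposited ranked lists also give the −log10 of the global IDR, and a score of 830 was an IDR of 0.01 in the lists of all 3 replicates. The deposited signal value of a peak is the output of the authors' peak caller. Its scale is not given in the sources used here, and it was used only to rank and describe peaks within a list.

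Which replicates stood behind each list of the whole series was worked out from its intervals. In the conservative list's ranked parent, 99.7% and 99.6% of the passing intervals were exactly those of replicates 1 and 2. Another ranked list matched replicates 1 and 3, a further list matched replicates 2 and 3, and the last matched no replicate (0.0394% and 0.0525% of intervals were those of replicates 1 and 2). Their thresholded lists held 6005, 4806, 4856 and 7462 peaks. The largest signal was 3250.98 in all 4 and 1204 or less in the replicate lists, so their positions and signals were taken to be those of peaks called on pooled reads. These sets share reads with the replicate lists and are not independent of them. Ranked peaks that reached the score but lie outside the thresholded lists were not used as peaks of these lists. They entered only where ranked lists were used, as in the alternative that counted ranked peaks of each replicate at an IDR of 0.01 or less. Its mean was 3793 peaks, against 3706 in the thresholded lists.

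Peaks were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. The genome was the RefSeq copy of the dm6 assembly. Peak ends fitted the lengths of all 6 main arms (2L, 2R, 3L, 3R, 4 and X). Genes and start sites came from Ensembl release 115, with 13945 protein-coding genes on the main arms. Locations were given in the order promoter (500 bp around a start site), 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic, and were compared with 1000 random placements on the same arms. Overlaps needed 1 bp and were compared with 100 random placements. Motifs were sought on both strands within 100 bp of a summit and within 100 bp of a point 1000 bp away on a random side, with an exact McNemar test adjusted over 20 motifs. A gene was bound if a summit lay in its body or up to 2 kb upstream, and lists were compared with 10000 random lists matched over 20 bins of gene length. The smallest p these tests can give are 0.002 for placements, 0.0099 for overlaps and 0.0002 for lists before adjustment. Shares have 95% Wilson intervals and densities exact Poisson intervals, which cover counting error only. Values over replicates are means with SD.

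The genes named are, by a rule set before the data were examined, zfh1, the 20 genes with the strongest peak found in all 3 replicates, the 5 with the most summits, up to 4 of the strongest bound members of each list, and 16 genes named in advance. A name in the lists that matched no annotated gene was dropped, which happened 3 times. Signals of gene lists are those of the strongest peak assigned to the gene.

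The scripts were tested on simulated data. With the motif planted in 10% of windows the ratio was 1.82. The value set beside it, also 1.82, was computed from the same windows and controls, so this checked only that planted copies were found. The promoter share was recovered as 41.7% where 42.4% was expected, and the overlap as 51.2% where 49.5% was expected. Of 300 unchanged lists of 20 genes drawn from 13945, 1.33% fell under the threshold of 0.05. Doubling the chance of being bound was found in 64% of lists of 15 genes and 100% of lists of 50, so small lists can miss such a change. Both checks of lists used simulated chances of being bound and p before adjustment. They therefore do not give the power of the adjusted test used for the calls.

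Alternatives set before the data were examined were the other deposited sets, peaks found in all 3 replicates, the strongest 50% of the peaks, leaving out each replicate (the mean over the lists of the remaining replicates, for results of the conservative set), other overlap rules, other windows, GC-matched windows and ranked peaks that did not pass as backgrounds, and other ways of assigning and matching genes. A score of 1000, windows matched on GC content and coding sequence, the list of each replicate alone, groups of equal size, ranked peaks that did not pass weighted to the summits and a proteasome list without paralogues named with R or T were added after seeing the data. Motif calls under the alternatives use adjusted p, a choice made after the unadjusted values had been seen.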

Results

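Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to find where a fusion of the transcription factor Zfh1 with green fluorescent protein lay on the genome of whole Drosophila melanogaster embryos collected from 0 to 24 h. Zfh1 is a zinc finger and homeodomain protein of the mesoderm and motor neurons, and the fly member of the ZEB family of repressors. The fusion was pulled down with an antibody against its fluorescent tag. The labels give 1 group of 3 biological replicates with no treated or control samples among them, so the design asks how well the replicates agree and where the fusion was found, and no comparison between groups was made. The deposited lists held peaks and no read counts, so the depth of each library is unknown. Peaks were described in the conservative set of the whole series, which held 6005 peaks, 6003 of them on the 6 main chromosome arms, and were set beside the thresholded list of each replicate.

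zfh1 itself was among the bound genes. The gene lies on arm 3R from 30765926 to 30789202, plus strand, in dm6 coordinates. It held 2 summits of the conservative set, both in introns and both inside peaks found in all 3 replicate lists. The stronger peak, from 30781672 to 30781883, had a signal value of 672.7 and ranked 167 of 6003. Its summit at 30781780 lay at -1478 bp from the nearest annotated start of a zfh1 transcript. The weaker peak, from 30775328 to 30775647, had a signal of 118 and ranked 3123. A peak from 30789432 to 30789751, with a signal of 224, lay just past the 3′ end of the gene and was also found in each replicate list. Replicate 3 alone had a further peak in the gene, from 30770119 to 30770402. The labels describe transgenic flies expressing the fusion, and the copy number of zfh1 sequence in them was not examined.

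**Figure D1:**
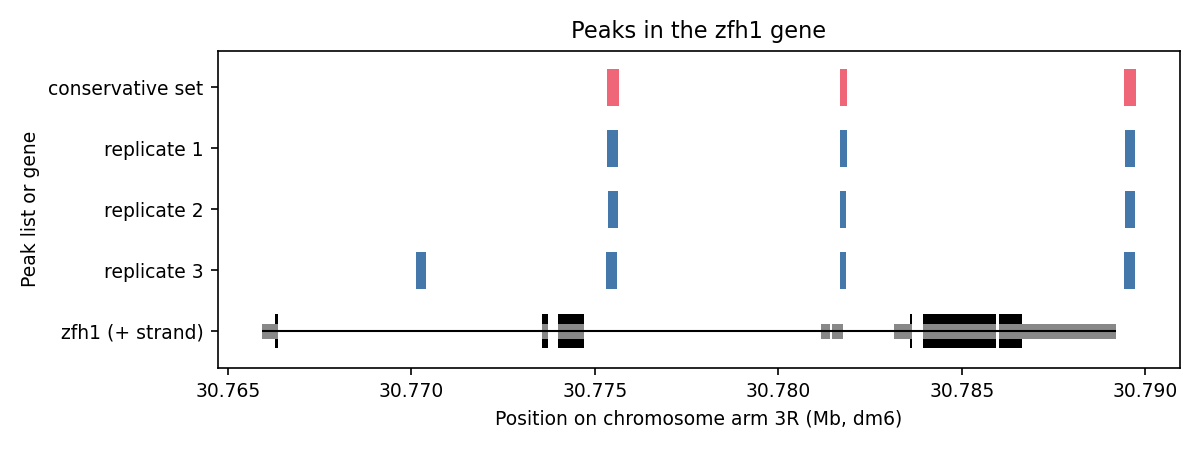
Peaks in and beside zfh1 on arm 3R (horizontal axis, position in Mb, dm6) in the conservative set and in each replicate's thresholded list (vertical axis). Grey blocks are exons and black blocks coding sequence; the peaks of the conservative set starting at 30775328, 30781672 and 30789432 were present in all 3 replicates.

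The strongest peaks sat at promoters, many of them between neighbouring genes. The highest signal, 3250.98, was at X from 2703723 to 2704044, between Ugalt, which carries nucleotide sugars into the Golgi, and eIF2Bbeta, a subunit of a translation initiation factor. CG14100 followed with 2966, then px with 2436 and the Polycomb group gene ph-p with 2273. The peak of CG11050, with a signal of 2206, was the only intronic peak among the 11 that carry the strongest 20 genes. Genes for mitochondrial ribosomal proteins lay at 3 of the next 4 peaks: mRpL41 shared a promoter peak of 2190.2 with CG8079, mRpS23 shared 1 of 2082 with CenG1A, and mRpS10 shared 1 of 2048 with Art3 and CG34316. The pair Tcs5 and CHMP2B had 2153, the trio CG7601, CIA30 and Gnpnat had 1927, and Chro and Ssl1, a chromatin protein and a subunit of the general transcription factor TFIIH, shared 1916. All 11 peaks were found in the 3 replicates, which the rule for choosing these genes required, and they were also ranks 1 to 11 of the whole set. The genes with the most summits were kirre, a cell adhesion protein of myoblast fusion, with 26, then sbb with 18, CG1677 with 17, and CHES-1-like, hth, px and ush with 13 each. These numbers were not adjusted for gene length, and longer genes hold more summits by chance. The kirre gene is long, spanning X from 2740384 to 3134532.

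Among the mesoderm regulators, tin, the heart and muscle homeobox gene, held 2 summits and a promoter peak of signal 765.7 (rank 126). Mef2, the muscle differentiation factor, held 7 summits with a strongest signal of 735.5 (rank 138), and twi held 2 with a strongest signal of 163. The strongest Mef2 summit lay at -1065 bp from the nearest Mef2 start and within 500 bp of a start site of another gene. Those strongest peaks of tin, Mef2 and twi were in all 3 replicate lists. sna held 2 summits and the fibroblast growth factor receptor gene htl held 1, with strongest signals of 105 and 89.2. Neither gene had a summit in the thresholded list of any replicate. The lipase gene bmm held 5 summits with a strongest signal of 223, Stat92E, the transcription factor of the JAK-STAT pathway, held 3 with 290.0, the corepressor gene CtBP held 2 with 176, and the Hippo pathway gene kibra held 4 with 154. The strongest peaks of CtBP and kibra were in 2 of the 3 replicate lists, and those of bmm and Stat92E in all 3. In the peaks analysed here, eve, Him, tup, exex, sav, E(spl)m6-BFM and the muscle myosin gene Mhc held 0.

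The 3 replicate lists differed in length and overlapped far more than random placement gave. Replicate 1 had 4055 thresholded peaks, replicate 2 had 4170 and replicate 3 had 2894, a mean of 3706 ± 706 (SD, n = 3). These were 4.18%, 4.31% and 2.64% of the ranked peaks of the same replicates. Of the peaks of replicate 1, 74.7% (95% Wilson interval 73.3 to 76.0) overlapped a peak of replicate 2 and 58.9% (57.3 to 60.4) a peak of replicate 3. Of those of replicate 2, 72.6% overlapped replicate 1 and 58.3% replicate 3. Of the shorter list of replicate 3, 82.5% overlapped replicate 1 and 84.5% replicate 2. The mean over the 6 directed pairs was 71.9%, against means of 1.13% to 1.62% for randomly placed lists (permutation p = 0.0099 for each pair, the smallest that 100 placements can give). Of the 1000 strongest peaks of a list, 97.9% to 99.9% overlapped a thresholded peak of each other list. Replicates 1 and 2 shared 825 peaks that replicate 3 did not pass, and 96.4% (94.9 to 97.4) of them overlapped a ranked peak of replicate 3, against 41.3% for random placement. Across the conservative-set peaks found in both lists of a pair of replicates, Spearman's rho of the replicates' signals was 0.83 for replicates 1 and 2, 0.81 for 1 and 3, and 0.81 for 2 and 3. Peaks are not independent replicates, so no p was computed for these.

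Of the 6003 peaks of the conservative set, 2218 (36.9%, Wilson interval 35.7 to 38.2) overlapped a peak in the thresholded lists of all 3 replicates, 1193 (19.9%) in 2, 1230 (20.5%) in 1 and 1362 (22.7%) in none. Peaks in none were not thereby absent from the replicates. Of the passing intervals of the set's ranked parent, 99.7% and 99.6% were ranked peaks of replicates 1 and 2. Support went with signal: the median signal was 245 for peaks in 3 lists and 77.8 for peaks in none. Of the 1201 strongest peaks 98.3% were in all 3 lists, and of the 1200 weakest 3.75% were. The group just above the weakest had 0.833%. The weakest include 165 peaks of signal below 20, described at the end, of which 163 lay within 1000 bp of a stronger peak. The intervals compared for the threshold of the conservative set were those of replicates 1 and 2, while its positions and signals were taken to be those of pooled reads.

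**Figure D2:**
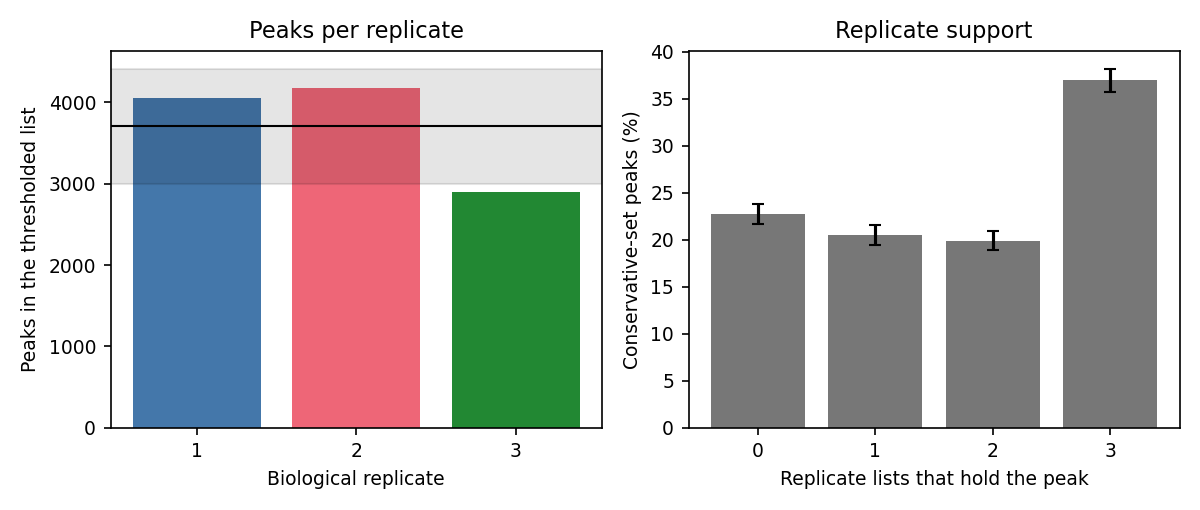
Left, thresholded peaks (vertical axis) in each of the 3 biological replicates, with the mean of 3706 as a line and 1 SD of 706 shaded. Right, share of the 6003 conservative-set peaks found in 0, 1, 2 or 3 thresholded replicate lists, with 95% Wilson intervals. The share is 36.9% for 3 lists and 22.7% for 0.

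Summits gathered at promoters and were scarce in coding exons and 3′ UTRs. Of the conservative set, 45.8% (Wilson interval 44.6 to 47.1) lay within 500 bp of an annotated transcription start, against 13.6% of randomly placed summits, 3.37 times as often (permutation p = 0.002, the smallest that 1000 placements can give). The share was 46.1% ± 2.18 over the replicate lists (SD, n = 3). Ranked peaks that did not pass the threshold had 15.8% of summits at promoters. Coding exons outside promoters held 1.62% of summits against 13.7% at random, 3′ UTRs 0.983% against 4.39%, introns 33.9% against 39.4% and intergenic sequence 16.2% against 27.4% (permutation p = 0.002 for each). In 5′ UTRs (0.600% against 0.773%, p = 0.146) and non-coding exons (0.933% against 0.818%, p = 0.336) no difference passed the permutation test. The replicate lists kept 0.749% ± 0.012 of their summits in coding exons and 34.5% ± 1.32 in introns (SD, n = 3). The 1201 strongest peaks had more promoter summits than the 1200 weakest, 52.0% against 46.9% (Fisher's exact test, two-sided, p = 0.0143), while the groups of equal size between them had 42.8% to 44.5%. The weakest include the 165 peaks of signal below 20, most of them beside a stronger peak.

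**Figure D3:**
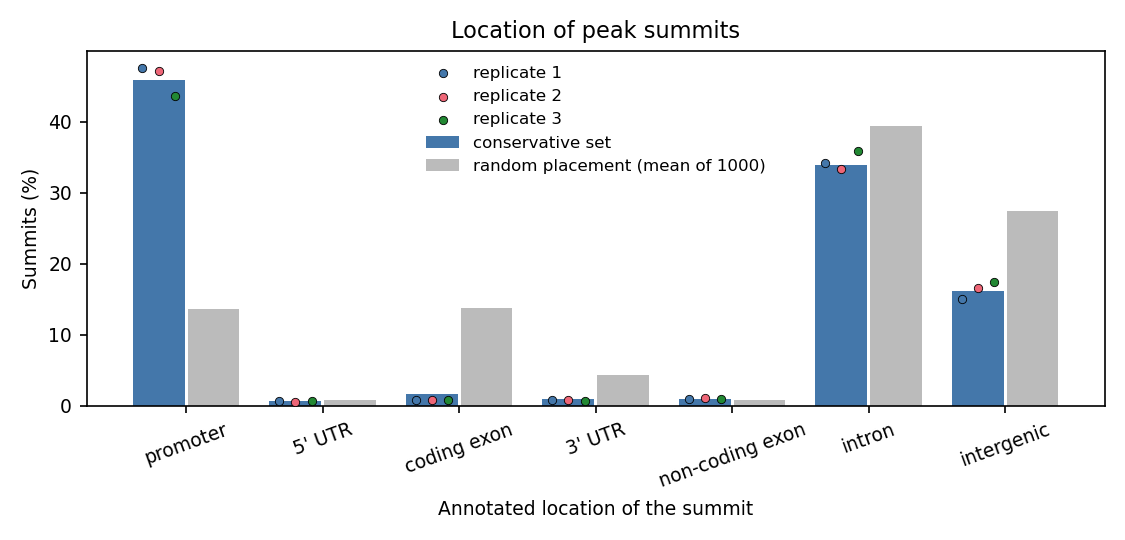
Share of summits (vertical axis, %) in each annotated location (horizontal axis) for the conservative set (blue bars), the mean of 1000 random placements (grey bars) and each replicate list (points). Promoters held 45.8% of summits against 13.6% at random, and coding exons 1.62% against 13.7%.

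The 5 large arms carried similar densities of peaks and the small chromosome 4 few. Densities ran from 43.5 peaks per Mb on 3R to 47.4 on 2L, with 45.7 on X. Chromosome 4 held 10 peaks, or 7.42 per Mb (exact Poisson interval 3.56 to 13.6), and 7.17 ± 2.38 per Mb in the replicate lists (SD, n = 3). Ranked peaks that did not pass were scarce there too, at 80.9 per Mb against 838 to 952 on the large arms. The density on X over that on the large autosomal arms was 1.01: X held 17.9% of the peaks on these arms (exact interval 16.97 to 18.9) and 17.8% of their length (exact binomial p = 0.723). The ratio was 1.05 ± 0.027 in the replicate lists (SD, n = 3). Set against ranked peaks that did not pass, which were themselves denser on X with a ratio of 1.09, the conservative set was lower on X, at 0.930 times their ratio (Fisher's exact test, p = 0.0348).

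The E-box that ZEB family proteins bind was no more frequent at summits than around them. CAGGTR lay within 100 bp of 10.4% of summits (Wilson interval 9.62 to 11.2) and in 12.8% of windows 1 kb away, a ratio of 0.811 (exact McNemar test, two-sided, p = 3.2e-05, adjusted p = 1.1e-04 over 20 motifs). The ratio was below 1 in 3 of 3 replicates, with a mean of 0.788 ± 0.034 (SD, n = 3). Of its forms, CAGGTG had a ratio of 0.751 (exact test, adjusted p = 6.0e-05) and CAGGTA 0.881 (adjusted p = 0.205). Against random windows of the same arm and GC content the ratio of CAGGTR was 1.01 (Fisher's exact test, adjusted p = 1) and that of CAGGTG 0.995, also not called. Summit windows had 38.6% GC against 42.8% in the windows 1 kb away. Against ranked peaks that did not pass, with 47.2% GC, the ratio of CAGGTR was 0.714 (Fisher's exact test, adjusted p = 3.5e-20). With 104779 of these peaks weighted to the arm, GC content and coding state of the summits, a test added after seeing the data, it was 1.09 (Cochran-Mantel-Haenszel chi-square test, n = 5998 summits, p = 0.0406). The share was 9.74% in the 1201 strongest peaks and 12.3% in the 1200 weakest (Fisher's exact test, two-sided, p = 0.0437). That p is close to the threshold and was 0.0505 with groups of equal size, a grouping tried after seeing the data. The difference was not called in the set of replicates 1 and 3 (p = 0.334) or of replicates 2 and 3 (p = 0.651, both Fisher's exact test). The weakest peaks include the 165 of signal below 20, most of them beside a stronger peak.

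Elements of housekeeping promoters were the most enriched of the 20 fixed motifs. TATCGATA, the DNA replication-related element bound by Dref, was in 3.27% of summit windows and 0.466% of those 1 kb away, a ratio of 7.0 (exact McNemar test, adjusted p = 6.2e-31), and 7.23 ± 2.45 over the replicates (SD, n = 3). YGGTCACACTR, the core promoter element called Motif 1, had a ratio of 5.60 (exact test, adjusted p = 2.8e-12) and 7.89 ± 3.01 over the replicates (SD, n = 3). The order of the pair changed with the background: against windows of equal GC TATCGATA had 4.67 (Fisher's exact test, adjusted p = 4.2e-24) and YGGTCACACTR 9.33 (adjusted p = 1.7e-15). In peaks found in all 3 replicates the ratios were 6.09 and 29, the latter over a share of 0.0451% in the windows 1 kb away. None of these backgrounds was matched on lying at promoters. Promoter summits against unbound promoters at the same distance from the start had ratios of 1.65 and 1.54 (Fisher's exact test, adjusted p = 9.2e-05 and 0.0254). The binding site of the muscle factor Mef2, YTAWWWWTAR, had a ratio of 1.63 (exact McNemar test, adjusted p = 3.7e-14). It stayed above 1 against windows of equal GC, at 1.27 (Fisher's exact test, adjusted p = 1.2e-04). The homeodomain core TAATTA had 1.25 (exact McNemar test, adjusted p = 8.8e-06) but 0.959 against windows of equal GC (Fisher's exact test, adjusted p = 0.576). GAGAGAG had 1.25 (exact test, adjusted p = 0.0358) and 1.71 against windows of equal GC (Fisher's exact test, adjusted p = 3.7e-07), but 1.03 ± 0.154 in the replicate lists (SD, n = 3) and 0.735 in peaks found in all 3 replicates (adjusted p = 0.101). CTAATTG (0.735, adjusted p = 0.0085) and CAGGTAG (0.651, adjusted p = 0.0358) were less frequent at summits by the exact test, and CAGGTAG lost its call in each of the other deposited sets. CTAATTG lost its call in peaks found in all 3 replicates (0.859, exact test, adjusted p = 0.599) and in the strongest 50% (0.789, adjusted p = 0.185). The other motifs, which included the E-boxes CATATG, CACGTG and CAAATG, did not pass the adjusted test. CAAATG was called below against windows of equal GC (0.856, Fisher's exact test, adjusted p = 1.2e-04) and in the set matching no replicate (0.914, exact McNemar test, adjusted p = 0.0227). Against ranked peaks that did not pass, CATATG had 1.36 (Fisher's exact test, adjusted p = 5.1e-09), CACGTG 0.761 (adjusted p = 0.0025), CAAATG 0.934 (adjusted p = 0.0188), AGATAA 1.59 (adjusted p = 1.1e-33) and CACACACA 0.829 (adjusted p = 0.0036), with GC content not matched. AGATAA was also called above in the set of replicates 1 and 3 (1.14, exact McNemar test, adjusted p = 0.0366) and in the strongest 50% (1.17, adjusted p = 0.0448). CACACACA was called below in peaks found in all 3 replicates (0.598, exact McNemar test, adjusted p = 0.0019), in the strongest 50%, in the set of replicates 2 and 3 and within 50 bp, but above within 250 bp (1.26, adjusted p = 1.3e-06). The E-box CAGCTG, at 1.12 (exact test, adjusted p = 0.0945), depended on peaks and background, with 1.53 against windows of equal GC (adjusted p = 2.4e-11) and 0.782 in peaks found in all 3 replicates (adjusted p = 0.0225). Among all strand-merged 6-mers ranked by enrichment over the windows 1 kb away, ACACTG came first, in 20.04% of summit windows against 8.03%, followed by AGTGTA and ACAGTG. CAGGTA ranked 1171 and CACCTG, the other strand of CAGGTG, 1609. Against windows matched on GC content and coding sequence, ACAGTG came first, and CAGGTA ranked 487 and CACCTG 829, with log2 ratios of 0.15 and 0.04.

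**Figure D4:**
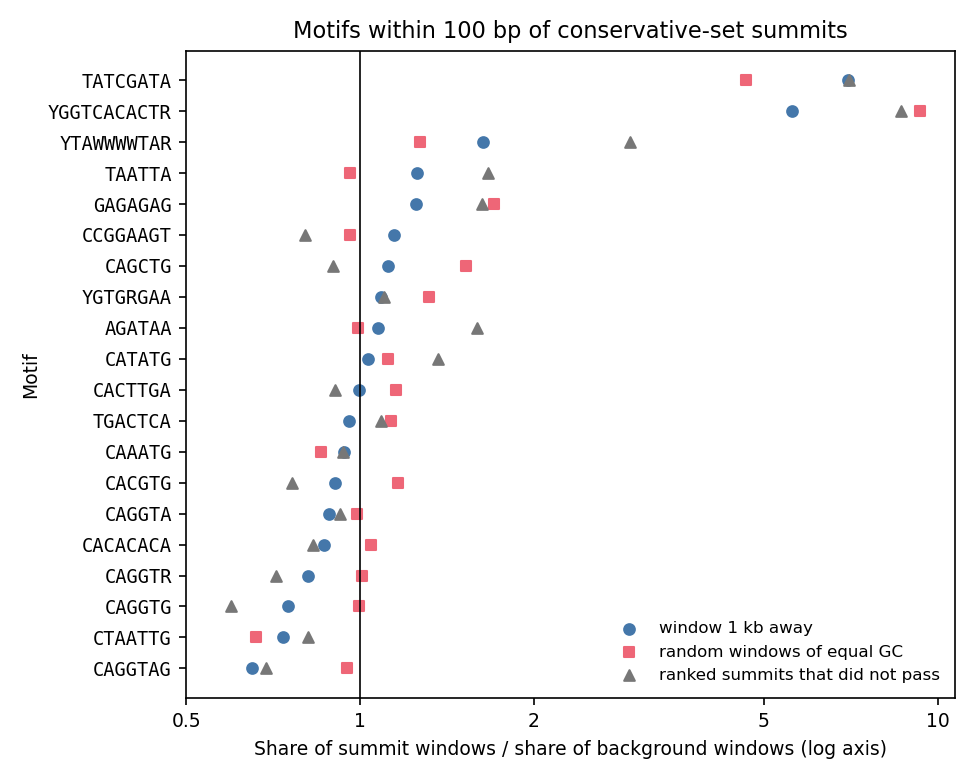
Ratio of the share of conservative-set summit windows holding each of 20 fixed motifs to the share of background windows (horizontal log axis; 1 is no difference), with 3 backgrounds shown by marker. TATCGATA and YGGTCACACTR lie farthest right, at 7.0 and 5.60 against windows 1 kb away; CAGGTR lies at 0.811 against those windows and 1.01 against windows of equal GC.

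Of 13945 protein-coding genes, 4511 (32.3%) held a summit in the gene or up to 2 kb upstream, and 84.7% of summits fell in such a region. No random share was set beside the 84.7%, and such regions cover much of the genome. Only 27.4% of randomly placed summits lay outside all annotated genes and promoters. The replicate lists bound 3444, 3609 and 2535 genes. Of 30 gene lists fixed beforehand, 4 were bound more often than random lists matched on gene length, 4 less often, and 22 did not pass the test (permutation tests, two-sided, Benjamini-Hochberg adjusted over the 30 lists). Random lists were not matched on position, so list members that lie close together were treated as independent genes. This concerns the E(spl) genes of the Notch list and the receptor and cuticle families, whose p may be too small.

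The genes for ribosomal proteins stood out most. Of the 92 cytosolic ribosomal protein genes 67 were bound, 72.8% against 23.4% in matched lists (adjusted permutation p = 0.001, the smallest possible), and 67.4% ± 4.35 in the replicate lists (SD, n = 3). RpL7, with a strongest signal of 849.8, RpS27 with 707, RpL23A with 620.4 and RpL34b with 555 led them, and the peak of RpL7 was also that of Sur. Of the 73 mitochondrial ribosomal protein genes 32 were bound, 43.8% against 19.6% (adjusted permutation p = 0.001), led by mRpL41, mRpS23 and mRpS10, named above, and mRpL23 with 1520.1. With each summit given only to its nearest start site, the mitochondrial list was no longer called (ratio 1.31, permutation test, adjusted p = 0.503), nor was it without length matching (ratio 1.36, Fisher's exact test, adjusted p = 0.0695). Proteasome genes were bound at 22.9% against 24.6% (adjusted permutation p = 0.974), with Rpn3, Rpn6, Prosbeta6 and Rpn13 the strongest. The list holds 16 paralogues named with R or T, such as Prosalpha3T and Rpt3R, of which 0 were bound; without them 11 of 32 genes were bound, 34.4% against 25.7% (adjusted permutation p = 0.506).

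Genes of the Notch and Hippo pathways were also bound above their matched lists. In the Notch list 14 of 22 genes were bound, 63.6% against 33.3% (adjusted permutation p = 0.0154), with E(spl)mdelta-HLH at 529.9, N at 473, numb at 469 and mam at 357. In the Hippo list 12 of 14 were bound, 85.7% against 47.8% (adjusted permutation p = 0.0202), with Diap1 at 441, ds at 423, ex at 419 and Mer at 247. Shares in the replicate lists were 50% ± 4.55 for Notch and 73.8% ± 8.25 for Hippo (SD, n = 3), above matched lists in 3 of 3 replicates for both. The Notch list was not called in the strongest 50% of the peaks (permutation test, adjusted p = 0.0607), in the deposited set that matched no replicate (adjusted p = 0.226) or in the list of replicate 2 alone (adjusted p = 0.178). The Hippo list was not called for summits within 1 kb of a start site (permutation test, adjusted p = 0.136).

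Receptor and cuticle gene families were nearly empty. Summits were found in 3 of 59 odorant receptor genes, 2 of 60 gustatory receptor genes, 2 of 60 ionotropic receptor genes and 3 of 70 genes of the Cpr cuticle protein family, against 27.1%, 27.6%, 30.5% and 23.9% in matched lists (adjusted permutation p = 0.001 for each). The few bound members were Or88a, Or9a and Or67d; Gr5a and Gr97a; Ir60e and Ir25a; and Cpr73D, Cpr64Aa and Cpr100A. The odorant list lost its call with the nearest start site (permutation test, adjusted p = 0.0913) and the cuticle list in peaks found in all 3 replicates (permutation test, adjusted p = 0.0907). Seminal fluid protein genes had 1 bound gene of 46, Sfp26Ad (2.17% against 12.6%, adjusted permutation p = 0.0852), and gap and pair-rule genes 1 of 15, opa (6.67% against 34.4%, adjusted permutation p = 0.0852). Both lists were called below with random lists matched on gene and flanking length (permutation test, adjusted p = 0.001 and 0.0452), and the seminal fluid list also in the deposited set that matched no replicate (adjusted p = 0.0405).

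Lists of muscle, mesoderm, blood and motor neuron genes did not pass the adjusted test. In mesoderm and early mesoderm signalling 12 of 18 genes were bound (66.7% against 46.8%, adjusted permutation p = 0.28), with tin, Mef2, zfh1 and the integrin gene if the strongest. The call of this list depended on the setting: it was above matched lists in the sets of replicates 1 and 3 (permutation test, adjusted p = 0.00857) and 2 and 3 (adjusted p = 0.0348), with the nearest start site (adjusted p = 0.026), with matching on gene and flanking length (adjusted p = 0.0236) and without length matching (Fisher's exact test, adjusted p = 0.0088). In muscle founder identity 8 of 18 were bound, led by org-1 at 861, lbl, kn and Poxm (44.4% against 49.5%, adjusted permutation p = 0.932). In muscle structure 6 of 25 were bound, with sls, Msp300, Zasp66 and Zasp52 ahead (24% against 45.1%, adjusted permutation p = 0.115), and the list was called below in the deposited set that matched no replicate (adjusted p = 0.0433). In myoblast fusion 10 of 16 were bound, with kirre, mbc, rols and siz ahead (adjusted permutation p = 0.534), and in the dorsal vessel list 6 of 19, with Sur, tin, sli and lbl ahead (adjusted p = 0.405). In gonadal mesoderm and cyst stem cells 10 of 15 were bound, with zfh1, Fas3, ken and chinmo ahead (adjusted permutation p = 0.636), and the list was called above in the set of replicates 1 and 3 (adjusted p = 0.0172), with matching on gene and flanking length (adjusted p = 0.0457) and without length matching (Fisher's exact test, adjusted p = 0.0178). In haemocytes 5 of 19 were bound, with Pvf3, ush, srp and lz ahead (26.3% against 47.5%, adjusted permutation p = 0.198), and in the motor neuron list 9 of 17, with Fas3, unc-5, fra and caps ahead (adjusted p = 1).

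The other signalling and regulator lists did not pass the adjusted test either. With random lists matched on gene and flanking length, however, Wnt, EGF and FGF, BMP, cell adhesion, ecdysone and repressor cofactor lists were called above (permutation tests, adjusted p = 0.00225, 0.006, 0.0452, 0.0452, 0.0162 and 0.0224), and EGF and FGF also in the sets of replicates 1 and 3 (adjusted p = 0.0469) and 2 and 3 (adjusted p = 0.0137). In the Wnt list 14 of 18 genes were bound (77.8% against 52.7%, adjusted permutation p = 0.124), with fz at 905, nkd, Wnt5 and Wnt4 ahead. The EGF and FGF list had 12 of 16, with aos, aop, spi and pnt ahead (adjusted permutation p = 0.292), the BMP list 10 of 15, with gbb at 1410.0, Mad, dpp and shn ahead (adjusted p = 0.298), and the JAK-STAT list 5 of 13, with Ptp61F, Socs36E, Stat92E and ken ahead (adjusted p = 0.905). Cell adhesion and polarity had 11 of 17, with baz at 957, par-6, crb and dlg1 ahead (adjusted permutation p = 0.751). Ecdysone response had 9 of 11, with Hr4, Hr3, EcR and Eip75B ahead (adjusted permutation p = 0.361), repressor cofactors 8 of 10, with gro, brat, Mi-2 and Smr ahead (adjusted p = 0.28), and Hox genes 6 of 8, with Antp, Ubx, lab and Abd-B ahead (adjusted p = 0.751). Lipid storage had 6 of 12, with Lpin, Lsd-2, bmm and mdy ahead (adjusted permutation p = 0.932). In neuroblasts and temporal factors 6 of 19 were bound, with grh, pros, scrt and insc ahead (adjusted permutation p = 0.724), and in the pan-neuronal and synaptic list 5 of 15, with elav, nSyb, fne and comt ahead (adjusted p = 0.28).

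**Figure D5:**
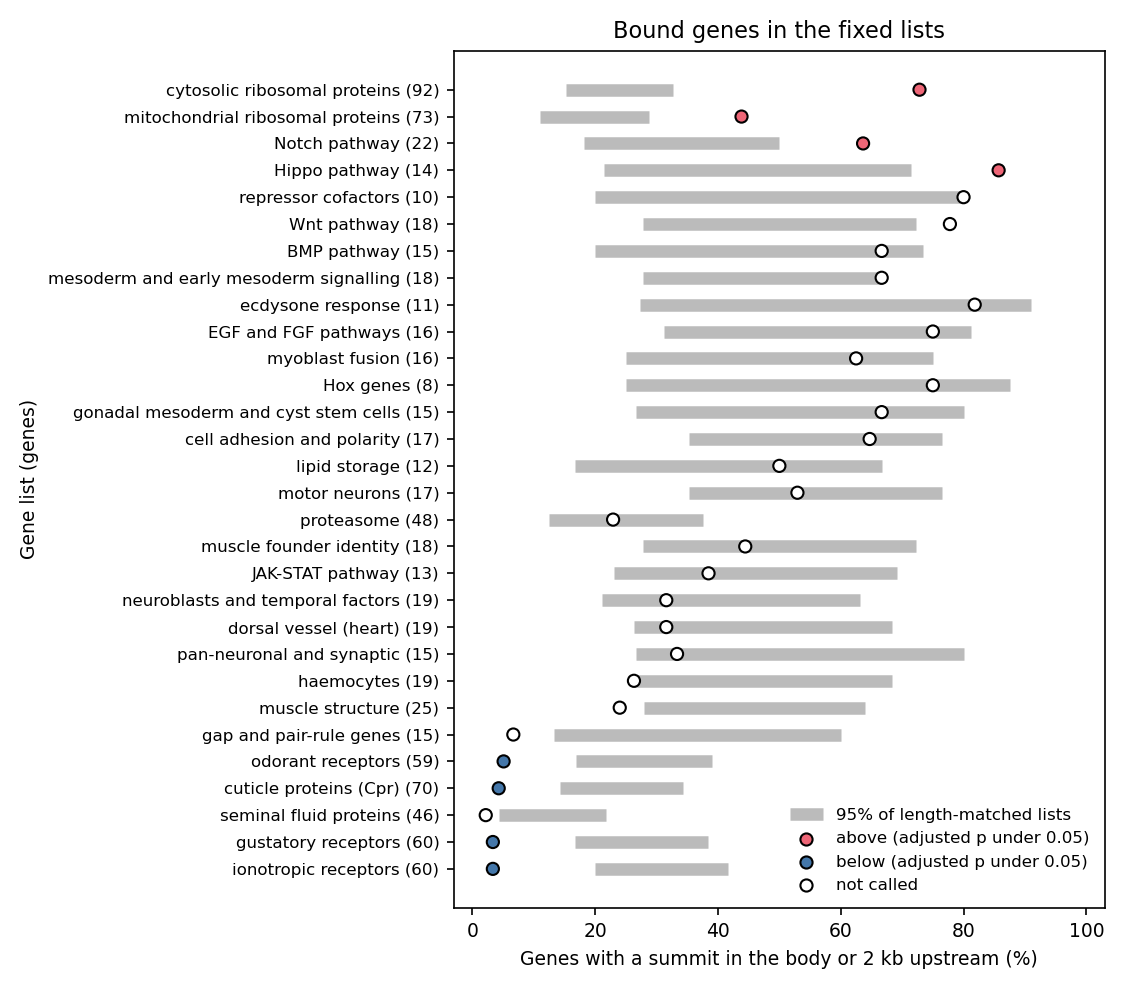
Share of genes bound (horizontal axis, %) in each of 30 fixed lists (vertical axis, number of genes in brackets), as points, with the range of 95% of length-matched random lists as grey bars. Cytosolic ribosomal protein genes, at 72.8%, lie farthest above their bar in ratio, and the receptor and cuticle families, at 3.33% to 5.08%, lie below theirs.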

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

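Replicate 3 had 8 thresholded peaks outside the 6 main arms, in sequence that the comparisons did not use, which is above the limit of 3 that a count of 0 allows. All 8 were on unplaced sequences of the X chromosome, with a highest signal of 71.4. Replicate 2 had 3 such peaks, with a highest signal of 83.1, and replicate 1 had 0. No explanation was tested.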

How the results depend on the processing

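Of 88 alternatives to the results that answer a comparison, 72 were counted as unchanged. For tested results this meant the same call, and the same direction wherever either result was called. For numbers of peaks or of gene lists it meant only a similar number, and the lists behind it could differ. With the nearest start site 4 lists were above, but only 3 of them were among the main 4. Peak numbers, pairwise overlap, peaks shared by 3 replicates, the promoter share and its excess in the strongest peaks were counted as unchanged under every alternative run. An IDR of 0.01, planned as stricter, is the authors' own threshold. Depth is unknown, so what it limits could not be weighed; the shared signal was rank-correlated at 0.806 to 0.833 when 1 replicate was left out. No paired analysis was possible because there is 1 group. Windows matched on GC and coding sequence, lists of single replicates, a score of 1000, groups of equal size, weighted peaks that did not pass and a proteasome list without paralogues were chosen after seeing the data.

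CAGGTR had a ratio of 0.904 in the set matching no replicate, no longer called, and was above 1 in GC-matched windows (1.01) and in GC- and coding-matched windows (1.06; 1.04 in the strongest 50%) and against weighted ranked peaks that did not pass (1.09), where matching itself removes the difference in base composition. The X ratio was 0.930 with ranked peaks that did not pass as background. The CAGGTR difference between the strongest and weakest peaks lost its call in the sets of replicates 1 and 3 (-1.36 points) and 2 and 3 (-0.629), in the strongest 50% (-0.183), with ranking by score (-1.65), where all peaks at the largest score tie, and with groups of equal size (-2.58, Fisher's exact test, p = 0.0505), and turned to 0.881 in peaks found in all 3 replicates; the cause was not tested. The number of lists above was 7 in the set of replicates 1 and 3, where mesoderm, gonadal mesoderm and EGF and FGF lists joined the 4, 13 without length matching, the mitochondrial ribosomal list no longer among them, and 12 with matching on gene and flanking length. Lists below were 6 in the set matching no replicate, where muscle structure and seminal fluid joined, 6 with gene and flanking length, where gap and pair-rule and seminal fluid joined, and 5 without length matching, with seminal fluid; the cause was not tested.

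Single motifs turned direction 12 times in 247 alternatives, and single gene lists 0 times in 361, counting only changes in which the main or the alternative result was called. Changes of side between uncalled values were left out. An example is CAGGTA, at 0.881 in the main setting and 1.11 with GC- and coding-matched windows. With GC-matched windows TAATTA was at 0.959. With GC- and coding-matched windows TAATTA was at 0.926, CAGGTG at 1.03 and CAGGTAG at 1.17, and CAGGTAG was at 1.18 in the set matching no replicate. In peaks found in all 3 replicates CAGCTG was at 0.782 and GAGAGAG at 0.735, which had 0.748 in the strongest 50%, 0.852 within 50 bp and 0.946 to 1.099 when 1 replicate was left out (0.946 without replicate 1). CAGCTG was at 0.896 against ranked peaks that did not pass, and CACACACA, at 1.26 within 250 bp, was called below 1 in 5 others, down to 0.598 in peaks found in all 3 replicates. The cause was not tested for these.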

Other observations

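The tests of dilution by weak peaks, of housekeeping promoters and of repeated elements in this part were chosen only after their results or closely related ones had been seen, as were the GC- and coding-matched windows, their repeated draws, the weighted peaks that did not pass, the proteasome list without paralogues and the divergent pairs at matched distance. All hypotheses here were found and tested on the same data.

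Promoter summits lay between divergent genes more often than other promoter positions. Of the 2750 promoter summits, 31.6% (95% Wilson interval 29.9 to 33.4) had start sites of protein-coding genes of both strands within 500 bp, against a mean of 9.25% and a highest value of 10.9% in 1000 random draws of promoter positions on the same arms. The share was 35.6% among the 624 promoter summits of the 1201 strongest peaks and 32.4% ± 1.64 in the replicate lists (SD, n = 3). The background mattered: for the 2566 summits with such a start within 500 bp the share was 33.9%, against means of 11.0% at random positions that near a start and 24.5% (highest value 26.9%) at the same distance from random start sites. Of these 2566, 29.3% (95% Wilson interval 27.5 to 31.1) lay between the starts of a divergent pair, each within 500 bp, against a mean of 16.3% and a highest value of 18.8% at that distance.

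Core promoter elements were more frequent at promoter summits than at unbound promoters or at promoter peaks that did not pass. TATCGATA was in 7.21% of 2566 promoter windows and in 4.36% of windows at the same distance from the start sites of unbound genes, a ratio of 1.65 (Fisher's exact test, p = 1.5e-05, adjusted p = 9.2e-05 over 6 motifs). YGGTCACACTR had a ratio of 1.54 (exact test, adjusted p = 0.0254) and the Mef2 site YTAWWWWTAR 1.36 (adjusted p = 0.0015). GAGAGAG had 1.47 (exact test, adjusted p = 0.0064), while CAGGTR had 0.890 (adjusted p = 0.176) and TAATTA 1.05 (adjusted p = 0.476). Against promoter peaks that did not pass, with GC content not matched, TATCGATA had 4.35 (Fisher's exact test, adjusted p = 5.3e-48), YGGTCACACTR 3.80 (adjusted p = 8.0e-19), TAATTA 1.98 (adjusted p = 4.1e-31) and CAGGTR 0.679 (adjusted p = 3.8e-12).

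Genes for small RNAs held some summits. Of 290 tRNA genes, 13.4% had a summit of the conservative set within 500 bp, against a mean of 4.72% and a highest value of 10% in 1000 random placements. The replicate lists, which are shorter, gave 5.06% ± 2.59 (SD, n = 3), with no random value for lists of that length. Of 32 snRNA genes 34.4% had one, against a highest random value of 21.9%, with 27.1% ± 6.51 in the replicate lists (SD, n = 3). For 269 snoRNA genes the share of 7.43% was within the random range, which reached 13.8%. Of 3261 genes of the broad ncRNA class 13.3% had one, against a highest random value of 10.9%, with 8.35% ± 1.28 in the replicate lists (SD, n = 3). Summits were 3.37 times as frequent at start sites of all genes as at random, which these placements do not allow for. The excesses therefore cannot be called particular to these classes.

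The 10-mer CACTGAGAGA was found while the most enriched 10-mers were ranked, and its values were seen before it was singled out; it ranked 11 of the 680 10-mers found in at least 40 summit windows, which overlap one another in sequence. It lay in 124 summit windows, 2.07% (Wilson interval 1.74 to 2.46), and in 8 of the windows 1 kb away, a ratio of 15.5 (exact McNemar test, p = 7.2e-28). In the replicate lists it was in 2.20% ± 0.116 of summit windows and 0.135% ± 0.083 of those 1 kb away (SD, n = 3). Away from promoters the share was 3.23%, at promoters 0.691%. Of 887 copies on the main arms, 130, or 14.7%, lay within 100 bp of a summit, while random placement put a copy in 7.62 windows on average and 17 at most. The copies lay a median of 64 bp from the summit, so the summits were not centred on them.

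Copies of a longer repeated element would share their flanks, but bases from 10 bp beyond the sequence, over 30 bp, were the same in 24.9% of comparisons between the 130 sites upstream and 28.7% downstream, with no long shared flank. Whether any enriched place holds it stays open: the share among passing summits was 10.6 times that of 0.194% in ranked summits that did not pass, but these lie near the 0.133% of the windows 1 kb away, and the sequence was chosen at passing summits. Mappability and the fusion's own sequence preference were not tested, and the design gives no group that would test a biological explanation. The protein that may recognise it stays open.

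The low frequency of CAGGTR at summits may follow from base composition. Against windows matched on GC content and on lying in coding sequence or not, the ratio was 1.06 (Fisher's exact test, p = 0.288), which was also the mean of 1000 draws of such windows, and against ranked peaks that did not pass it went from 0.714 to 1.09 (Cochran-Mantel-Haenszel chi-square test, p = 0.0406) when these were weighted likewise. Dilution by weak peaks stays open: the share in the 1201 strongest peaks differed from that in the 1200 weakest by -2.59 percentage points (Fisher's exact test, p = 0.0437), but the windows 1 kb away differed too, at 12.2% and 14.3%, and the call was lost in 5 alternatives and turned direction in 1. Over 1000 draws of matched windows the ratio averaged 1.18 in the strongest, with p under 0.05 in 13.7% of draws, and 1.05 in the weakest, and the log2 ratios differed by 0.16 (95% bootstrap interval -0.42 to 0.76). No test here says whether Zfh1 binds CAGGTR at some sites, and no biological explanation was tested.

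The frequent binding at cytosolic ribosomal protein genes was not shared by proteasome genes. If every housekeeping promoter gave signal alike, these would be bound as often as the 72.8% of ribosomal genes, but 22.9% of the list was (Fisher's exact test, p = 1.6e-08), and 34.4% without its 16 paralogues named with R or T (95% Wilson interval 20.4 to 51.7; Fisher's exact test, p = 2.2e-04). Peaks of neighbours assigned to short genes would lose the call once each summit is given to its nearest start site, but the cytosolic list then had a ratio of 3.57 (adjusted permutation p = 0.003). Signal that follows transcription level or open chromatin without the fusion protein stays open, since expression data, input and embryos without the fusion were not used here, and no biological explanation was tested.

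Of the 6003 conservative-set peaks, 165 (2.75%) had a signal below 20, against a median of 122 in the set, and 68.5% of these carried the largest score. Of the 165, 163 lay within 1000 bp of a stronger peak of the set, at a median of 205 bp over all 165, and 63 overlapped no thresholded replicate list. All 165 were among the 1200 weakest peaks, the group set against the strongest above for promoters and CAGGTR.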
